A study of Homo sapiens with 2 samples.

How the data were processed

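RNA-seq gene tables of 2 human liver cancer lines, SKHEP1 and HepG2, were used, with 1 library of unmodified cells per line. Groups were taken from the cell line labels. Per the labels' protocols, RNA was purified with a column kit and sequenced from stranded mRNA libraries. Per the submitters' processing notes, the tools were cutadapt, STAR, RSEM and DESeq2 and the genome build was hg19; versions, the gene annotation and the strand setting of RSEM are not given in the sources used here, so values of antisense and overlapping genes are uncertain. Per the file headers, the deposited tables are RSEM gene results with expected counts, that is, estimated reads per gene that need not be whole. The same deposited tables give TPM (transcripts-per-million) and FPKM (values scaled by effective length and aligned reads), as well as isoform-weighted gene lengths and other length columns, per the file headers. Each table lists 57820 genes by an identifier and symbol. Expected counts were whole to the decimals given for 95.2% of the listed genes in SKHEP1 and 95.0% in HepG2, genes at 0 included.

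Expected counts were rounded to whole numbers and scaled to counts-per-million (CPM) of the TMM effective library size with edgeR 4.0.16 in R 4.3.3. The TMM factors were 1.01 for SKHEP1 and 0.99 for HepG2. The most abundant gene took 1.07% of the counts in SKHEP1 and 2.88% in HepG2. Genes with an expected count of at least 10 in either library were compared, and a ratio of at least 4 was counted as higher in a line. A count under 3 in one library was replaced by a floor of 3 counts per library. Such ratios, given as at least a fold, are lower bounds of the observed ratio and not 95% limits. Exact 95% lower limits are smaller, such as 159600 for ALB against 196300. Where a ratio is given for a gene with 1 to 3 counts, it is the raw ratio with its interval. Genes of the Y chromosome, XIST and TSIX were left out, 29 of them past the count minimum. Intervals at 95% are exact Poisson intervals for a level and exact conditional Clopper-Pearson intervals for a ratio. No difference between the lines was tested, since neither has a replicate. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

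In total, 23 gene lists were written from textbook knowledge: p53 targets, p53 and its regulators, long noncoding RNAs, hepatocyte transcription factors, liver secreted proteins, coagulation and complement, liver metabolism, oncofetal genes, endothelial, mesenchymal, epithelial, stellate, and blood and immune markers, cytokines, interferon response, Wnt targets, cholesterol synthesis, proliferation, cancer testis antigens, HOX genes, housekeeping genes, mitochondrially encoded mRNAs, and stress genes. Some genes stand in more than 1 list, such as MDM2. Each list was summarised by its members past the count minimum, its median log2 ratio, and the percentile of that median among 10000 random lists matched in 20 expression bins. PURPL was matched by its identifier, and PECAM1, PANDAR and LINCR-0002 were not analysed here. Gene types and chromosomes were taken by stable identifier from GENCODE release 29, which matched 14993 (97.3%) of the 15407 genes compared. No coordinates are given, since that release uses another genome build.

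The named genes were fixed by rule, and some genes it takes are not reported here: PURPL, MDM2, CDKN1A, HUWE1 and MYBBP1A; the 6 most abundant genes per library; the 8 genes per direction with the largest lower bound of the ratio and at least 1000 counts in the higher library; and per list up to 4 members with the largest log2 ratio and at least 100 counts, with up to 2 that went furthest against the list. Genes named outside this rule were chosen after their values were seen: CDKN2A, SERPINA1, CDH5, KDR, ESAM, NEAT1, MALAT1 and the genes that open the closing observations. The design, lists, naming rule and alternatives were fixed before the data were examined. The alternatives were total counts or DESeq2 1.42.0 size factors in place of TMM, the deposited TPM or FPKM values, the deeper library thinned to the depth of the other, a prior count of 2 in place of the floor, unrounded counts, count minimums of 50 and 1, limits of 2-fold and 8-fold, the lower bound of the ratio, protein-coding genes only, and the mean in place of the median. For the lists, a further alternative took all members with at least 1 count.

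The comparison was tested on simulated counts for the real genes at the real depths, with 200 genes changed 8-fold. Of these, 99.0% were found at least 4-fold apart in the right direction, 8 of 14796 unchanged genes were at least 4-fold apart, and 95.5% of the intervals of unchanged genes held the true ratio. The noise was Poisson only, and unchanged genes had the same mean profile in both libraries. Variation between cultures or libraries was not simulated, so these shares are not error rates of the real comparison. Reads shared between near-identical genes were divided by RSEM, so values of such genes are uncertain, among them C4A and C4B, ORM1 and ORM2, HSPA1A and HSPA1B, and the GAGE family. The long-read isoform profiles and the PURPL knockdown lines that belong to the study's design were not analysed here.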

Results

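Poly(A)-selected, stranded RNA-seq was carried out on unmodified cultures of 2 human liver cancer lines, with 1 library per line. HepG2 is labelled as hepatocellular carcinoma. SKHEP1, a line established from a liver adenocarcinoma, is labelled as endothelial cells. The stated purpose was to examine the expression and transcript variants of PURPL, a long noncoding RNA induced by p53. The SKHEP1 library held 19940557 expected counts and the HepG2 library 22477757, and 13831 and 13405 genes, respectively, reached 10 counts. A level of 3 counts, taken as the floor, corresponded to 0.149 counts-per-million (CPM) in SKHEP1 and 0.135 in HepG2. With a single library per line no difference has a replicate check. The 95% intervals given cover counting error only. They may be too narrow even for that, since PCR reads without molecular identifiers are not independent molecules.

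PURPL was expressed in both lines at a low and similar level, slightly higher in HepG2. The gene is listed under its older symbol LINC01021 (ENSG00000250337.1, a lincRNA on chromosome 5, with 6 transcripts in the table). It had 206 expected counts in SKHEP1 (exact Poisson interval 178.8 to 236.1) and 296 in HepG2 (263.2 to 331.7). These correspond to 10.2 (8.85 to 11.7) and 13.3 (11.9 to 15.0) CPM, a HepG2 over SKHEP1 ratio of 1.31 with a counting interval of 1.09 to 1.57. The deposited TPM values for PURPL were 15.3 and 21.5. PURPL ranked 37 among the 301 lincRNAs with 10 or more counts in SKHEP1, and 12 among 305 in HepG2. Genes were also selected by their geometric mean level across the 2 lines, and 3190 lay within 2-fold of PURPL's mean. Of these, 71.4% were further apart between the lines than PURPL was. A gene abundant in only a single line can enter this set, which may raise that share. The isoform-weighted length RSEM assigned to PURPL was 1250 bases in SKHEP1 and 1150 in HepG2, and individual variants were not analysed here.

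**Figure D1:**
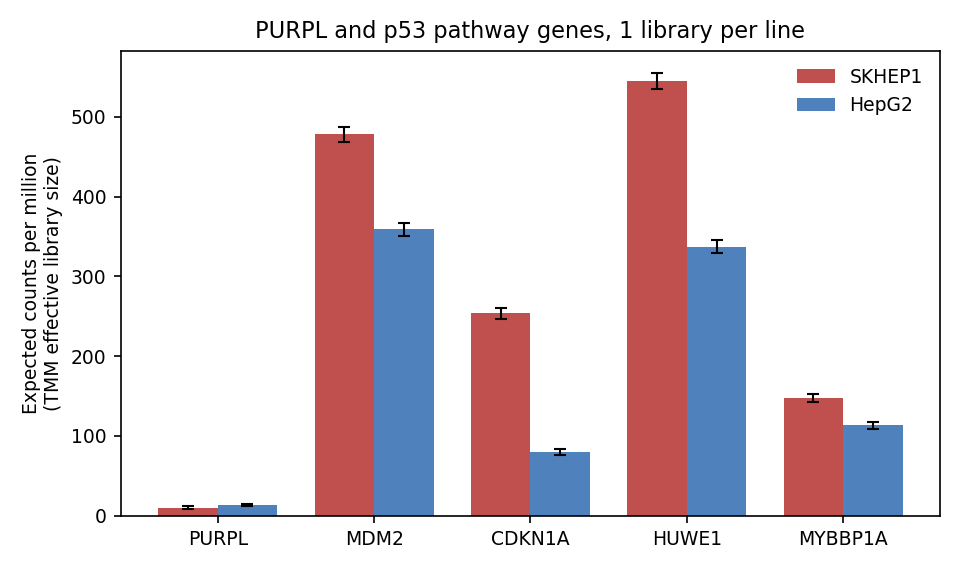
Levels of PURPL and 4 genes of the p53 pathway in SKHEP1 and HepG2, in CPM of the TMM effective library size, with 1 library per line. Error bars are exact Poisson 95% intervals of the count; PURPL lies at 10.2 and 13.3, and the 4 protein-coding genes are all higher in SKHEP1.

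CDKN1A, MDM2, HUWE1 and MYBBP1A, named before the data were examined for their ties to p53, were expressed in both lines and were each higher in SKHEP1, by less than 4-fold. The cell cycle inhibitor CDKN1A, or p21, a p53 target, was 3.20-fold higher in SKHEP1 (interval 3.03 to 3.38), at 254 against 79.3 CPM. MDM2, the ubiquitin ligase that degrades p53, was 1.33-fold higher (1.29 to 1.37). HUWE1, another ubiquitin ligase of p53, was 1.61-fold higher (1.57 to 1.66), and MYBBP1A, a nucleolar p53-binding protein, 1.30-fold (1.24 to 1.37). On the log2 scale, MDM2 (-0.41) and MYBBP1A (-0.38) did not exceed the median of the 20 housekeeping genes (-0.47). Their shifts are therefore not particular to p53 genes. HUWE1 (-0.69) and CDKN1A (-1.68) did exceed that median. Of 36 p53 targets, 32 lay within 4-fold. The kinase PLK2 was 44.0-fold higher in SKHEP1, and PLCL2, at 205 counts in SKHEP1 and 0 in HepG2, at least 75.0-fold higher. NINJ1, a mediator of plasma membrane rupture, was 14.0-fold higher in HepG2, and the sestrin SESN1 4.25-fold. The median log2 ratio of the targets, HepG2 over SKHEP1, was -0.26, at percentile 6.03 of 10000 random lists matched on expression, a description of these 2 libraries. Of 17 expressed members of the list of p53 and its regulators, 15 lay within 4-fold and 2 were higher in HepG2. USP7, the deubiquitinase of MDM2 and p53, was 4.11-fold higher in HepG2 (3.93 to 4.30), and CDKN2A, at 0 counts in SKHEP1 and 19 in HepG2, was not past 4-fold with TPM or FPKM values or tested with a minimum of 50 counts. TP53BP1, a DNA damage response protein, was 2.88-fold higher in SKHEP1. The median of these regulators was -0.37 (percentile 9.23), whereas their mean was 0.06.

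Across the transcriptome the lines differed widely. Of 15407 genes with at least 10 counts in either library, 2547 (16.5%) were at least 4-fold higher in SKHEP1 and 1988 (12.9%) in HepG2, while 10872 (70.6%) lay within 4-fold. These were 2151 and 1560 protein-coding and 243 and 281 long noncoding genes. The other line had under 3 counts for 1390 of the genes higher in SKHEP1 and for 876 of those higher in HepG2. In SKHEP1 the most abundant genes were THBS1, which encodes the matrix glycoprotein thrombospondin 1, EEF1A1, VIM, GAPDH, ACTB and ACTG1. In HepG2 they were ALB, APOB, EEF1A1, FN1, FTL and PEG10. THBS1 was at 10540 CPM in SKHEP1 and 566 in HepG2. PEG10, an imprinted retrotransposon-derived gene, was 33.6-fold higher in HepG2, and FTL, the ferritin light chain, 4.32-fold.

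The largest gaps were for genes abundant in one line and at or near 0 counts in the other. VIM, which encodes the intermediate filament vimentin, had 144720 counts in SKHEP1 and 2 in HepG2, a ratio of 79440 with a counting interval of 21990 to 656000. CAV1, the main caveolar protein, had 43159 and 1. CD44, a hyaluronan receptor, had 47924 and 6, and the membrane peptidase gene MME 23211 and 2. MSN, which encodes moesin, had 22621 and 2 counts, and LDHB, a lactate dehydrogenase subunit, 20639 and 1. The proteoglycan SRGN and the matrix peroxidase PXDN had 0 counts in HepG2 and against the floor were at least 5274-fold and 4106-fold higher in SKHEP1. In the other direction ALB, which encodes serum albumin, had 646438 counts in HepG2 and 0 in SKHEP1, and against the floor of 3 counts was at least 196300-fold higher in HepG2. APOB, the structural protein of low-density lipoprotein, was at least 142100-fold higher. A2M, TF, AHSG, APOH, GPC3 and ITIH2 also had 0 counts in SKHEP1 and lay between 47486 and 99125 counts in HepG2.

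**Figure D2:**
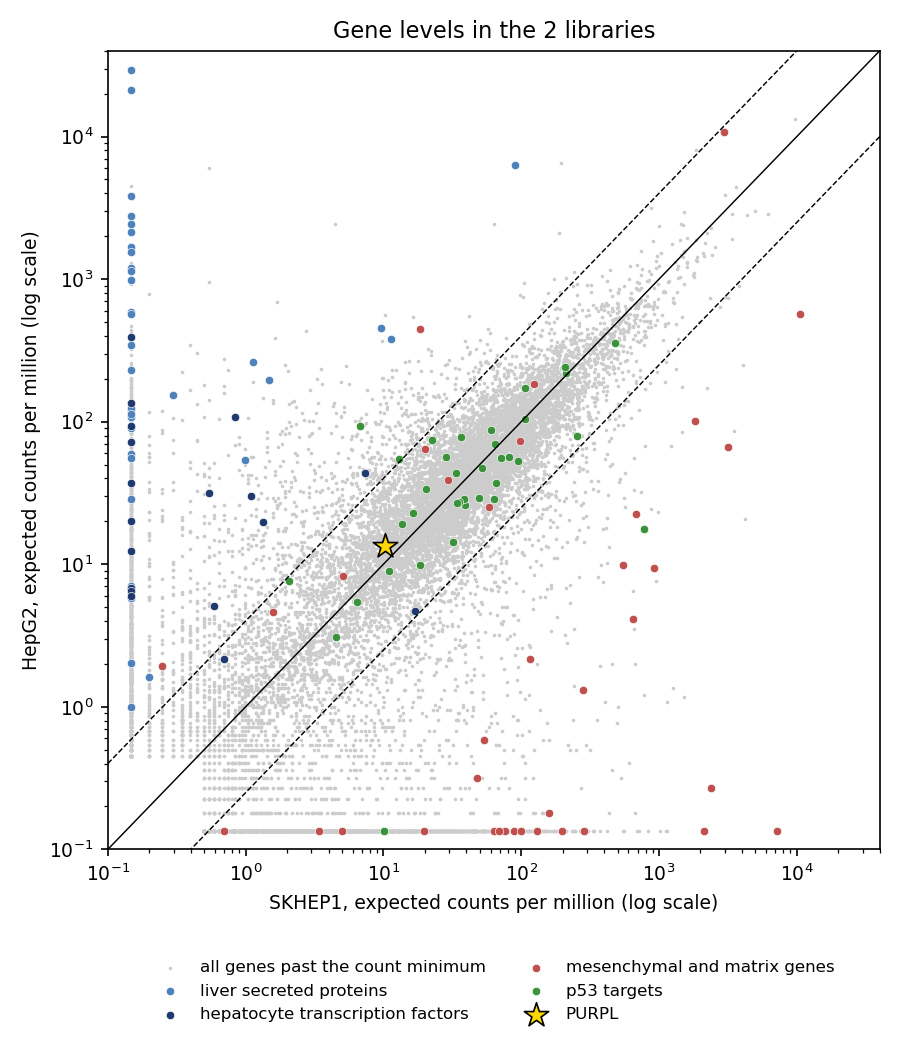
Level of each gene past the count minimum in SKHEP1 (horizontal) and HepG2 (vertical), in CPM on log scales, with 1 library per line and genes under 3 counts drawn at the floor. Dashed lines mark 4-fold; all 37 liver secreted proteins lie above the upper line, 27 of 37 mesenchymal and matrix genes lie below the lower line, and PURPL (star) lies close to the diagonal.

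HepG2 expressed most of the listed hepatocyte genes, which SKHEP1 had at few or no counts. All 37 genes for liver secreted proteins were higher in HepG2, with a median log2 ratio of 9.58 (percentile 100). SERPINA1, or alpha-1-antitrypsin, was the member most abundant in SKHEP1 with 1817 counts, and was 70.6-fold higher in HepG2. Of 18 expressed hepatocyte transcription factors, 16 were higher in HepG2 and none in SKHEP1, with a median of 5.69 (percentile 100). HNF4A, a master regulator of hepatocyte identity, had 8689 counts in HepG2 and 0 in SKHEP1, at least 2638-fold higher. PROX1 and the bile acid receptor NR1H4 were likewise at 0 in SKHEP1, with 3007 and 2074 counts in HepG2.

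Plasma and metabolic genes of the liver followed the same direction. Of 32 expressed coagulation and complement genes, 29 were higher in HepG2 and 1 in SKHEP1, with a median of 7.17 (percentile 100). F2, or prothrombin, had 7586 counts in HepG2 and 1 in SKHEP1, a ratio of 6910 with an interval of 1240 to 273000. Complement factor I (CFI) was at 4422 and 0 counts. C1R lay within 4-fold and was 1.67-fold higher in SKHEP1. Of 37 genes for bile acid, drug and amino acid metabolism, 11 were under 10 counts in both libraries. Of the 26 others, 22 were higher in HepG2 and 2 in SKHEP1. The list median was 4.63 (percentile 100), or 3.64 with a minimum of 1 count. HPD and HGD, enzymes of tyrosine breakdown, had 3409 and 2560 counts in HepG2 and 0 in SKHEP1. GSTA1, which shares reads with its near copy GSTA2 and is uncertain for that reason, was at 2422 and 0 counts. TDO2, an enzyme of tryptophan breakdown, was at 641 counts in SKHEP1 and 0 in HepG2, at least 235-fold higher in SKHEP1.

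Most oncofetal genes and Wnt targets were higher in HepG2, while most cholesterol synthesis genes lay within 4-fold. Of 16 expressed fetal liver and oncofetal genes, 12 were higher in HepG2 and 4 lay within 4-fold, with a median of 5.16 (percentile 100). AFP, the fetal serum protein alpha-fetoprotein, had 133342 counts in HepG2 and 11 in SKHEP1, an 11040-fold difference with an interval of 6171 to 22120. GPC3, a cell-surface glypican, had 48686 counts in HepG2 and 0 in SKHEP1, PEG3 had 24115 and 0, and LIN28B, an inhibitor of let-7 maturation, 4147 and 0. HMGA2 and SOX9 were expressed in both lines and were 1.35-fold and 1.14-fold higher in SKHEP1. Of 15 expressed Wnt targets, 12 were higher in HepG2 and 2 in SKHEP1, with a median of 6.67 (percentile 100). The Wnt feedback inhibitor NKD1 had 5759 counts in HepG2 and 3 in SKHEP1, a ratio of 1749 (598 to 8481). NOTUM and the stem cell receptor LGR5 were at 0 in SKHEP1, and RNF43 was at 1 count there against 2825 in HepG2. The transcription factor LEF1 was 20.1-fold higher in SKHEP1, and the secreted Wnt inhibitor DKK1 2.10-fold. Of 23 cholesterol synthesis genes, 4 were higher in HepG2, 1 in SKHEP1 and 18 within 4-fold, with a median of 0.70 (percentile 99.9). The sterol reductase gene TM7SF2 was 19.9-fold higher in HepG2 (14.4 to 28.2), and the mevalonate pathway gene MVD 9.50-fold. INSIG1, the sterol sensor that retains SREBP in the endoplasmic reticulum, had 3816 counts in SKHEP1 and 2 in HepG2, a ratio of 2095 (579 to 17300).

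Most mesenchymal genes were higher in SKHEP1, and more epithelial genes were higher in HepG2 than in SKHEP1. Of 37 expressed mesenchymal and matrix genes, 27 were higher in SKHEP1, 2 in HepG2 and 8 within 4-fold, with a median of -5.80 (percentile 0). The fibrillar collagen gene COL3A1 had 5765 counts in SKHEP1 and 0 in HepG2, at least 2110-fold higher. TGFBI, a secreted matrix protein, was 24.4-fold higher in HepG2, and FN1, or fibronectin, 3.65-fold. Of 26 expressed epithelial genes, 14 were higher in HepG2, 2 in SKHEP1 and 10 within 4-fold, with a median of 3.27 (percentile 100), a mean of 1.98, and a median of 0.98 with a minimum of 1 count. CDH1, or E-cadherin, had 439 counts in HepG2 and 0 in SKHEP1, and the tight junction gene CLDN4 was 112-fold higher in HepG2 (51.4 to 307.5). The keratin gene KRT7 and the claudin gene CLDN7 had 1276 and 889 counts in SKHEP1 and 0 in HepG2.

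Few endothelial markers were detected in either line. Of 31 matched markers, 18 were under 10 counts in both libraries, among them CDH5, or VE-cadherin, with 1 count in SKHEP1, and the VEGF receptor gene KDR with 0. Of the 13 others, 6 were higher in SKHEP1 and 4 in HepG2. ENG, the TGF-beta co-receptor endoglin, was 117-fold higher in SKHEP1 (74.1 to 198.6), ROBO4 94.1-fold (36.4 to 347.5) and EGFL7 39.1-fold, and thrombomodulin (THBD) had 117 counts in SKHEP1 and 0 in HepG2. ESAM, an endothelial adhesion molecule, had 16 counts in SKHEP1 and 144 in HepG2. The median of the 13 markers was 0.71 (percentile 81.3), but their mean was -1.06, so the list has no single direction, and with a minimum of 50 counts the median was -3.98. Of 10 expressed hepatic stellate and fibroblast markers, 5 were higher in SKHEP1 and 3 in HepG2, with a median of -1.07 (percentile 23.2) but a mean of 0.45, and with a minimum of 50 counts a median of 1.40. With the deposited TPM or FPKM values 3 were higher in each line, so this list has no single direction either. RGS5, a pericyte marker, was 15.8-fold higher in SKHEP1, the transcription factor GATA4 4.28-fold higher in HepG2, and the secreted glycoprotein gene RELN had 28967 counts in HepG2 and 3 in SKHEP1. Blood and immune cell markers were mostly undetected, with 15 of 20 under 10 counts in both libraries. Of the 5 others, 4 lay within 4-fold, among them the lysosomal gene CD68, and LYZ, or lysozyme, was at 33670 counts in HepG2 and 0 in SKHEP1, with a list median of 1.98 (percentile 94.6), or 0.45 from TPM. With DESeq2 size factors 3 of the 5 were past 4-fold, all higher in HepG2.

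Most cytokine and HOX genes were higher in SKHEP1. So were 7 of 18 expressed interferon response genes, against 16.5% of all genes compared. Of 18 expressed cytokine and chemokine genes, 14 were higher in SKHEP1 and 2 in HepG2, with a median of -5.59 (percentile 0). CXCL1, a neutrophil attractant, had 6094 counts in SKHEP1 and 1 in HepG2, a ratio of 6690 (1200 to 264300). The interleukin genes IL1B and IL1A had 5392 and 1185 counts in SKHEP1 and 0 in HepG2, and CXCL6 had 2240 and 0. CCL20 went the other way, with 1 count in SKHEP1 and 1034 in HepG2, as did IL11 at 9 and 105. Of 18 expressed interferon response genes, 7 were higher in SKHEP1, 1 in HepG2 and 10 within 4-fold, with a median of -1.24 (percentile 0.78), and by the mean the list lay inside the range of random lists. IFIT2 was 139-fold higher in SKHEP1 (53.9 to 511.7), OAS2 180-fold (61.4 to 877.9), and IFI44 was at 182 counts against 0. MX2 had 3 counts in SKHEP1 and 986 in HepG2, a ratio of 299 (102 to 1454). Of 27 expressed HOX genes, which set positional identity, 22 were higher in SKHEP1 and 1 in HepG2, with a median of -5.41 (percentile 0). HOXB9 and HOXC10 had 813 and 524 counts in SKHEP1 and 0 in HepG2, HOXB7 had 1455 and 1, and HOXD1 had 461 counts in HepG2 and 0 in SKHEP1. Of 22 cancer testis antigens, 20 were under 10 counts in both lines. PRAME was 527-fold higher in SKHEP1, and GAGE1, a member of a family of near-identical copies and therefore uncertain, was at 113 counts against 0, with a median of -7.21 for the 2 genes (percentile 0.84), or -0.14 for all members with at least 1 count.

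Most long noncoding RNAs of the list lay within 4-fold between the lines, as did 70.6% of all genes compared. Of 24 expressed members, 18 lay within 4-fold, 4 were higher in HepG2 and 2 in SKHEP1, with a median of -0.21 (percentile 24.4), or -0.05 from TPM, and a mean of 0.05. NEAT1, the scaffold of paraspeckles, was 2.47-fold higher in SKHEP1, and MALAT1 1.63-fold. KCNQ1OT1, an imprinted antisense transcript, was 17.1-fold higher in HepG2 (11.7 to 25.9), a value that is uncertain because it overlaps KCNQ1 and the strand setting is not given, and the snoRNA host gene SNHG5 5.89-fold. CRNDE had 109 counts in SKHEP1 and 0 in HepG2. CYTOR, listed as LINC00152, was 6.76-fold higher in SKHEP1, but shares reads with a near copy and is uncertain.

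All proliferation, housekeeping and mitochondrially encoded genes of the lists lay within 4-fold. The 25 proliferation genes had a median of -0.10 (percentile 42.7) and a mean of 0.15. The mitotic kinase PLK1 was 3.30-fold higher in HepG2 and the replication clamp PCNA 2.40-fold. The 20 housekeeping genes had a median of -0.47 (percentile 1.51). B2M, the light chain of HLA class I, was 3.18-fold higher in SKHEP1, HPRT1 2.75-fold and GAPDH 2.17-fold, while EEF1A1 was 1.36-fold higher in HepG2. The 13 mitochondrially encoded mRNAs had a median of 0.74 (percentile 99.9), and MT-ND4, a subunit of respiratory complex I, was 2.36-fold higher in HepG2. Of 15 stress and immediate early genes, 13 lay within 4-fold and 2 were higher in SKHEP1, with a median of -0.35 (percentile 17.8), or -0.04 from TPM. The AP-1 subunit JUN was 4.72-fold higher in SKHEP1 (4.33 to 5.15), and CHAC1 had 112 counts in SKHEP1 and 1 in HepG2. TRIB3, a target of the integrated stress response, was 3.24-fold higher in HepG2.

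**Figure D3:**
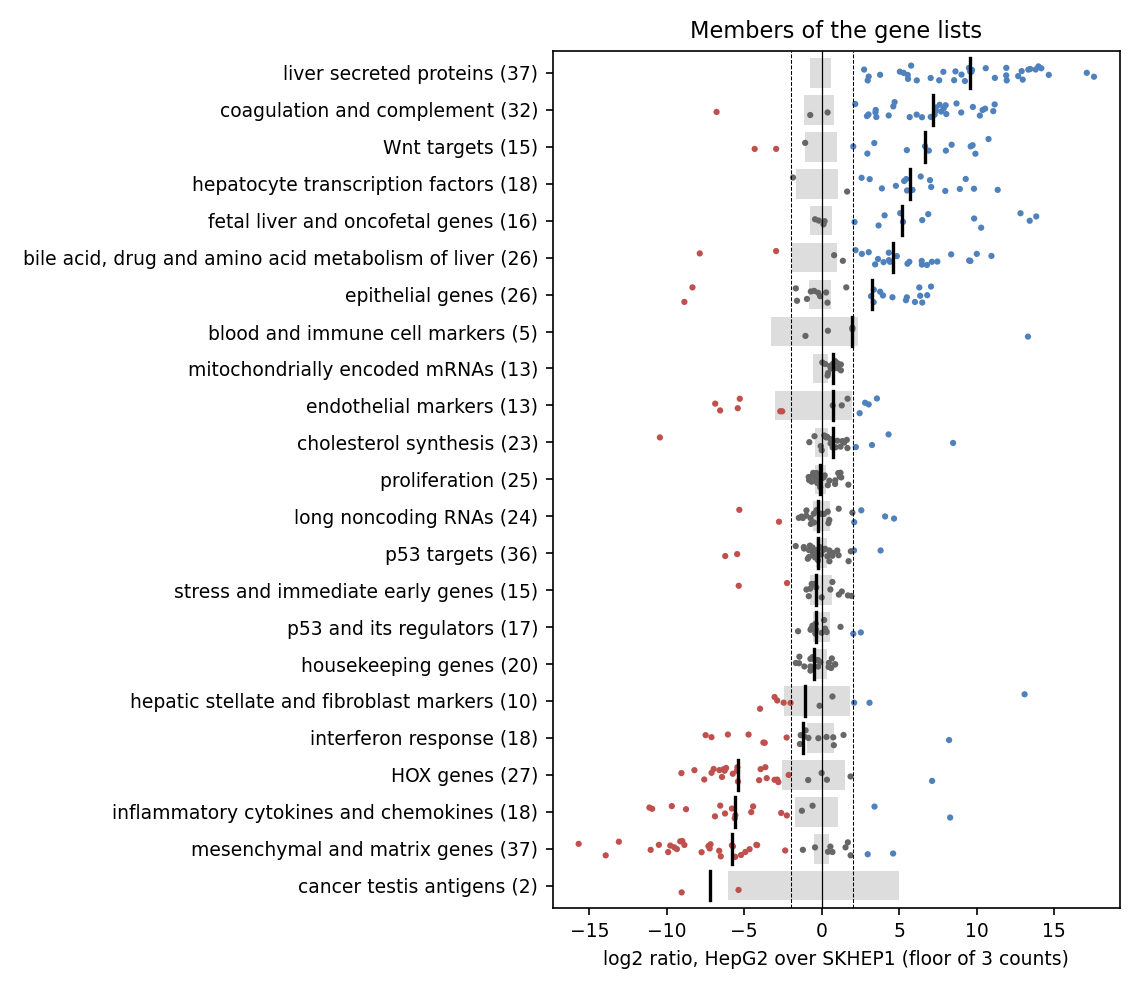
Log2 ratio of HepG2 over SKHEP1 for each expressed member of the 23 gene lists, with the number of expressed members in parentheses, red and blue points at least 4-fold apart, a black bar at the list median and a gray band for the central 95% of medians of matched random lists. Liver secreted proteins have the highest median at 9.58, mesenchymal and matrix genes lie at -5.80, and the p53 targets lie at -0.26.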

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

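All alternatives reported here were planned before the data were examined. PURPL remained slightly higher in HepG2 under all 7 alternatives, with a log2 ratio between 0.35 and 0.50. The number of genes at least 4-fold higher ranged from 1793 to 2569 in SKHEP1 and from 1513 to 2058 in HepG2 when the scaling, the values, the count minimum, the floor, the gene types or the use of the lower bound was altered. With a limit of 2-fold the counts were 3856 and 3598, and with a limit of 8-fold 1769 and 1247, which follows from the limit itself. None of the 123 genes followed under the naming rule crossed the 4-fold limit or changed sign under any of 7 alternatives. Of 253 list values recomputed, none reversed among lists outside the range of random lists, and 246 kept their side of that range. The housekeeping median moved into the range with TPM (-0.46), FPKM (-0.45) or the mean (-0.34). The cancer testis median did so with a count minimum of 1 (-0.14) and with all members of at least 1 count (-0.14). The interferon list moved into the range with the mean (-1.65). The blood and immune list moved out of it with the mean (3.33). The stellate median was 1.40 with a minimum of 50 counts, and the blood and immune median -0.14 with a minimum of 1. The endothelial median, inside the range in each setting, was -3.98 with a minimum of 50 counts and -0.14 with a minimum of 1. The cause was not tested. Scaling by total counts or by DESeq2 size factors shifted the median gene by -0.04 and 0.04. No paired analysis was possible because each line had 1 library. Depth limits the rarest genes, since a gene at 10 counts in one line cannot reach 4-fold against the floor of 3 counts in the other.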

Other observations

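The genes named first were chosen after their values were seen. SKHEP1 expressed HLA class II genes, which present antigen to helper T cells. All 11 class II genes past the count minimum were higher in SKHEP1, and 8 of them had 0 counts in HepG2. HLA-DRA had 2780 counts in SKHEP1 and 0 in HepG2, HLA-DPA1 had 1611 and 1, and HLA-DRB1, which shares reads with related copies, had 1329 and 0. CD74, the class II invariant chain, was expressed in both lines, 3.99-fold higher in SKHEP1. Of 10 genes of the S100A family of calcium-binding proteins, 6 were higher in SKHEP1 and 2 in HepG2. S100A6 was 35.8-fold higher in SKHEP1, while S100A1 was 286-fold higher in HepG2 (111 to 1051). Of 20 integrin subunit genes, 9 were higher in SKHEP1 and 1 in HepG2, with ITGA3 at 23003 and 24 counts. Of 9 annexin genes, 6 lay within 4-fold, but ANXA1 had 16799 counts in SKHEP1 and 2 in HepG2.

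A set of genes was present in one line at 1000 counts or more and at 0 in the other. There were 80 such genes in SKHEP1 and 94 in HepG2. CD81, a tetraspanin and receptor of hepatitis C virus, had 3427 counts in SKHEP1 and 0 in HepG2. The detoxification gene GSTP1 had 3093 and 0, and NSD1, a histone methyltransferase, 2330 and 0. NQO1, a quinone reductase induced by NRF2, had 13009 counts in HepG2 and 0 in SKHEP1. Among long noncoding RNAs, LINC00261 had 2478 counts in HepG2 and 0 in SKHEP1. The pseudogene RPL41P1 was listed at 15978 and 9552 counts, close to the 15840 and 9654 of its parent RPL41. Reads shared between such near copies were divided by RSEM, so the level of the pseudogene itself is uncertain.

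Of the tests that follow, those of GC content, of carry-over and of the endothelial markers were chosen after the result was seen. Gene levels shifted together by chromosome: on chromosome 16, the median log2 ratio of 634 protein-coding genes was 0.81 in favour of HepG2, and on chromosome 20 it was 0.78, while on chromosome 12 it was -0.62. A chance draw of genes is argued against by 15 of 22 autosomes lying outside the Bonferroni range of matched random lists, although neighbouring genes are not independent and these ranges are too narrow. A bias with GC content is argued against by a chromosome 16 median of 0.78 after the medians of 20 GC bins were subtracted, with 14 autosomes still outside their ranges. Of the 634 genes on chromosome 16, 76.8% were higher in HepG2, and its genes within 4-fold had a median of 0.68. Neither value tests a few strongly differing genes as the source of its shift. A few genes cannot set a median of 634, and a majority higher in HepG2 follows from that median. A difference in copy number between the 2 lines may account for the shift of chromosome 16, where all 3 consecutive parts had medians of the same sign (0.70, 1.09 and 0.69) outside their ranges, but no DNA was measured. The same held for 7 of the 15 shifted autosomes, chromosome 16 included, whereas the parts of chromosome 6 had medians of -0.19, 0.06 and 0.66 and those of chromosome 17 -0.53, -0.21 and 0.09.

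Some of the most abundant genes of one line had a few counts in the other, such as AFP with 11 counts in SKHEP1. If carry-over of reads between the 2 libraries were the source of AFP's counts, ALB would be predicted at 26.6 counts or more in SKHEP1, and it had 0, with an exact Poisson 95% upper limit of 3.69. That argues against carry-over as the source of these AFP counts. Genes with 1 to 3 counts, such as CAV1 in HepG2, are too few to decide. No biological explanation was tested.

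Of 31 matched endothelial markers, 10 reached 10 counts in SKHEP1, the library labelled as endothelial cells, and 9 did so in HepG2. An exchange of the 2 libraries is argued against by ALB, at 0 counts in the library labelled SKHEP1. The upper limits of 30 markers lay below 22.7 CPM, the median level of genes with at least 10 counts. That count cannot decide whether too little depth hid markers. Any marker under 10 counts must lie there, and the other 9 of these 30 were seen. Since 10 counts corresponded to 0.49 CPM in SKHEP1, a marker at that median level would have been seen. The 10 markers at 0 counts had an upper limit of 0.18 CPM, and levels under that limit stay open. A culture without most of the endothelial programme also stays open, since the 10 markers seen are the pattern itself.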
